A study of Mus musculus with 44 samples.

How the data were processed

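Total RNA of liver, white adipose tissue and brain cortex was labelled as biotinylated cRNA and hybridised to Illumina mouse beadchips in 1 colour, per the labels' protocols. The beadchip's probes are beads that each carry 1 oligonucleotide, and a probe's signal is the mean brightness of its beads. The deposited data were 2 tables over the same 25697 probes and 44 arrays. The first held the authors' non-normalized intensity of each probe on each array, without background subtraction (the lowest value on any array was 39.4). Beside each intensity the authors deposited a detection score under the name of a p-value. Its rank correlation with the signal was 0.966 or higher on every array, so the bright probes had the high scores, and the score was read as 1 minus the detection p. The second table held the authors' processed values, made with lumi per the submitters' processing notes, which give no version. Its columns held the same set of values within each tissue (the sorted values differed by at most 0.0113, against 0.648 over all arrays), so the authors' log2 values were quantile normalized within tissue. Their order on each array was that of the non-normalized signal of the same array, with a rank correlation of 1. The medians were 7.35 in liver, 7.09 in fat and 7.25 in brain. Whether the transform was a plain log2 or a variance stabilising one is not given in the sources used here, so the scale of these deposited log2 values stays partly unknown, and they were used only as an alternative. The scanner, its software and a slide or scan date are not given in the sources used here.

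Samples were grouped by the tissue and genotype in their labels. The number in each label was taken as the animal's number and used as the replicate number. The p-values measure the spread between these animals. No signal column was identical to another. The tissue markers were compared with the tissue in each label, which is how the mismatch between probe identifiers and values was found.

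Gene symbols came from the platform annotation given for the probes. Of 25697 probes, 23978 had 1 symbol, 1719 had none and 0 had several, and 23962 were matched to a current symbol through their Entrez identifier, giving 16593 different symbols. No coordinates are printed, because no genome build is named for the values.

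All values were computed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. The intensities were background corrected by the normexp method of neqc, with the negative control mean and SD estimated from the detection p-values, an offset of 16 was added, and the values were quantile normalized within each tissue and put on a log2 scale. A probe entered a tissue's test if its detection p was under 0.05 on at least as many arrays as a group held (8 in liver and brain, 6 in fat). Of the detected probes with the same deposited symbol, the 1 with the highest mean signal was kept. This left 8260 probes in liver, 9099 in fat and 9280 in brain. KO was compared with WT within each tissue with lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences of the KO effect between tissues were interaction contrasts in 1 limma fit over the 44 arrays with a mean for each of the 6 groups. Gene lists with at least 5 tested probes were tested with camera at a preset correlation of 0.01, and with an estimated correlation as an alternative, which also gave 0 lists past the threshold in each tissue. Adjustment was made separately over the pathway lists, the marker lists and the neighbours of Surf1.

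The groups, the tests, the alternatives and the gene lists were fixed before the data were examined. The rule for named genes fixed then was to name Surf1, in each tissue the 10 higher and 10 lower genes of largest change among those past the threshold, or up to 5 of smallest p in a direction where fewer passed, up to 4 members of a list, and 5 genes per interaction. That rule was not followed once the marker genes showed that the deposited identifiers did not name the values. Symbols are printed only for Surf1 and for the marker and housekeeping genes that show the mismatch, and the genes among these were chosen after their values were seen. At most 2 probe identifiers higher and 2 lower are given per comparison, those of smallest p. Keeping 1 probe per symbol also rests on those names. It was left as fixed, and with all detected probes as separate tests 0 of 11117 passed in liver, 5 of 12468 in fat and 0 of 12648 in brain.

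Samples of different tissues with the same number came from the same animal if the numbers are animal numbers, so the pairing was examined. The correlation of their deviations from the group means had a median of 0.09 between liver and fat (12 animals, -0.22 to 0.40), 0.01 between liver and brain (9 animals) and 0.00 between fat and brain (9 animals). The animal was used as a random block in an alternative fit of the interactions (duplicateCorrelation, consensus correlations of 0.105, 0.108 and 0.103).

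The steps were tested on simulated data with independent noise at the observed spread. Of 100 probes changed by 1 log2, 81 were recovered among 8260 probes in liver, 90 among 9099 in fat and 81 among 9280 in brain. Of 100 changed by 2 log2, 100, 98 and 99 were recovered. The false calls numbered 7, 14 and 7. Real arrays share structure between probes that this simulation did not hold.

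The alternatives were no background correction, cyclic loess, joint normalization of the 44 arrays, the authors' processed values, no filter on dim probes, detection on every array, all detected probes, no intensity trend, array weights, 1 fit over the 44 arrays, each sample left out in turn, the animal number range as a covariate, and animals below 300 alone. Animals above 500 alone, the fits without the 4 brain arrays with the fewest detected probes, the interactions and liver lists in animals below 300 and the interactions over all probes were added after the data had been seen. For each model count, 100 seeded splits of the samples were refitted, and for liver, brain and the differences between liver and fat and between fat and brain also 100 splits that kept the genotypes balanced as observed within each number range. For these 2 differences 100 more exchanged genotypes between animals with the same tissues and number range, so that each animal kept 1 genotype. Both were added after the first had been seen. Whether the identifiers were displaced was tested with a model that took an offset along the probe order from neighbouring probes of the same symbol. On simulated displaced identifiers it gave an offset to 22808 of 25697 probes, 98.9% of them exact. There all probes of a symbol were copies of 1 real probe plus noise, and the offset changed at the rate the model assumes. On the real arrays 11758 probes received an offset, and the simulation does not give the accuracy there. Several versions of this model and its settings were tried while the marker counts were seen.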

Results

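Gene expression was measured in 3 tissues of female B6D2F1/J mice aged 8 to 12 months that either carried a disrupted Surf1 gene (KO) or were wild type (WT). Surf1 encodes an assembly factor of cytochrome c oxidase, complex IV of the mitochondrial respiratory chain. The series had 44 arrays in 6 groups, 8 WT and 8 KO livers, 6 WT and 6 KO samples of white adipose tissue (fat) and 8 WT and 8 KO samples of brain cortex. Samples are named here as in their labels, by tissue, genotype and a number that was taken as the number of the animal. The 44 arrays then came from 23 animals, of which 12 gave more than 1 tissue and 9 gave all 3. Each array was an Illumina beadchip with 25697 probes. The share of probes detected above background was 42.2% ± 4.93 (SD, n = 8) in WT liver, 43.9% ± 2.24 (SD, n = 8) in KO liver, 49.2% ± 1.28 (SD, n = 6) in WT fat, 48.9% ± 1.69 (SD, n = 6) in KO fat, 48.5% ± 3.64 (SD, n = 8) in WT brain and 49.8% ± 1.77 (SD, n = 8) in KO brain. The number of arrays per group limits the precision of every comparison.

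The probes named for the targeted gene were read first. The deposited identifiers paired 2 probes with Surf1, and both lay at background in WT and KO alike. ILMN_2657141 was detected on 0 of 16 liver, 0 of 12 fat and 0 of 16 brain arrays, and ILMN_2883561 on 1 of 16, 0 of 12 and 1 of 16. In WT samples ILMN_2657141 had a normalized log2 signal of 4.73 ± 0.19 (SD, n = 8) in liver, 4.55 ± 0.07 (SD, n = 6) in fat and 4.52 ± 0.12 (SD, n = 8) in brain. In fits over all probes, KO minus WT was 0.03 (SE 0.11), -0.02 (SE 0.05) and 0.02 (SE 0.06) for this probe, and 0.00 (SE 0.10), -0.04 (SE 0.08) and -0.13 (SE 0.10) for ILMN_2883561. Probes without signal in wild-type tissue cannot tell the genotypes apart, so these values check no label. The marker genes below also show that the deposited identifiers did not name the values, so these probes need not measure Surf1.

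Genes with a known tissue of expression did not show it under the deposited identifiers. Albumin (Alb), the main plasma protein made by hepatocytes, was detected on 1 of 16 liver arrays, where its mean signal exceeded that of 41% of probes, and its signal was 107 ± 5.41 (SD, n = 12) in fat and 98.9 ± 12.4 (SD, n = 16) in brain. Transthyretin (Ttr), another plasma protein of the liver, was detected on 0 of 16 liver arrays, with a signal of 134 ± 37.5 (SD, n = 16). Adiponectin (Adipoq), a hormone secreted by adipocytes, read 3240 ± 1740 (SD, n = 16) in liver against 604 ± 281 (SD, n = 12) in fat. Snap25, a presynaptic protein of neurons, was detected on 0 of 16 brain arrays, with a signal of 90.5 ± 8.64 (SD, n = 16). A probe named for the glycolytic enzyme Gapdh read 6420 ± 3000 (SD, n = 16) in liver, 353 ± 99.1 (SD, n = 12) in fat and 154 ± 35.4 (SD, n = 16) in brain. A probe for the ribosomal protein Rps3 read 2330 ± 1250 (SD, n = 16) in liver and 103 ± 7.42 (SD, n = 16) in brain.

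The marker lists gave the same picture as groups. Of 11 probes with hepatocyte names, 0 were over 1 log2 higher in liver than in both other tissues, and 1 was detected there (9.1%, against 43.3% of all probes). Detection went the other way for some lists, with 13 of 17 oligodendrocyte probes detected in brain (76.5%, against 49.2% of all probes) and 6 of 8 adipocyte probes in fat (75%, against 48.5%). The counts over 1 log2 higher were 0 of 23 for bile acid and lipoprotein genes, 3 of 38 for xenobiotic metabolism, 0 of 8 for adipocytes in fat, and, in brain, 0 of 12 for neurons, 0 of 17 for oligodendrocytes, 1 of 15 for astrocytes and 3 of 30 for neuronal and synaptic genes. Together 7 of 154 marker probes were higher in their own tissue, and the share among all probes gave 6.5. Among the 100 brightest probes of each tissue, 0 carried a name from that tissue's own lists. The deposited identifiers therefore could not be used to name genes for the values of either deposited table, and the comparisons between KO and WT are given by probe identifier alone, without gene symbols. Each identifier was taken to mark the same probe on every array, whichever probe that is, which was not tested. If so, the difference of a probe between genotypes does not rest on its name. The counts of probes tested and passed do rest on the names in part, because 1 probe was kept per symbol.

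**Figure D1:**
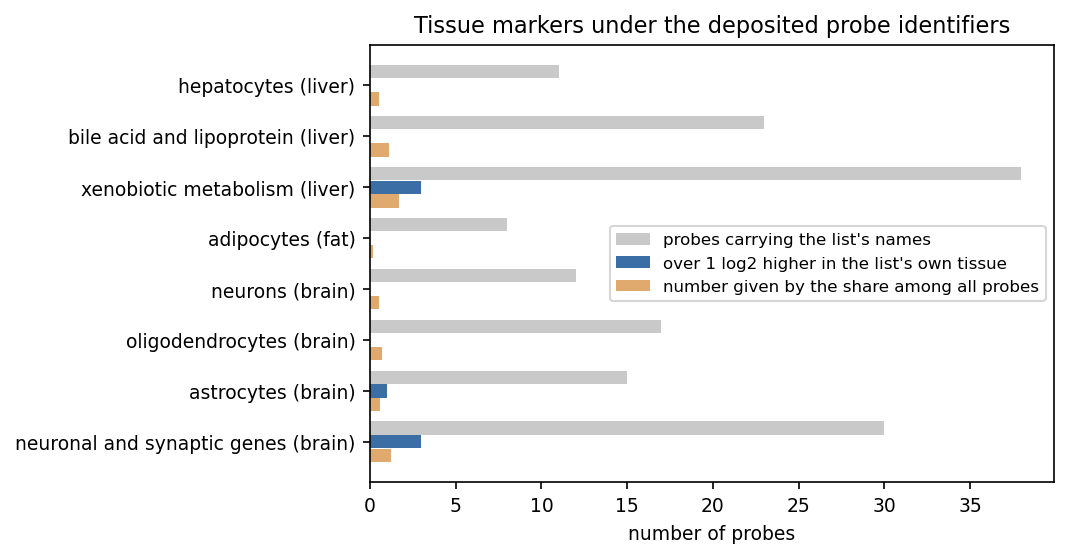
Number of probes (horizontal axis) that carry the names of each marker list (grey), the number of them over 1 log2 higher in the list's own tissue than in both others (blue), and the number that the share among all probes would give (orange). In all, 7 of 154 marker probes were higher in their own tissue, against 6.5 from the share among all probes.

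The arrays also differed in ways that genotype did not cover. Animal numbers fell below 300 or above 500, and all 12 fat arrays were from animals below 300. In liver the 4 arrays above 500 were dimmer, with 38.9% of probes detected in Liver_WT_581, 31.3% in Liver_WT_679, 40.8% in Liver_Surf1_KO_597 and 40.2% in Liver_Surf1_KO_598, against 43.1% to 46.7% on the other arrays. The 4 brain arrays with the fewest detected probes were Brain_WT_136 (45.9%), Brain_WT_138 (45%), Brain_WT_165 (42.8%) and Brain_Surf1_KO_175 (45.7%). The other brain arrays had 48.8% to 52.9%, so the arrays with the fewest detected probes were mostly WT. They were not clearly dimmer, with median signals of 97.8 to 112.7 against 99.3 to 120.8 on the other brain arrays. The first principal component held 44.4% of the variance in liver and 55.7% in brain, and in both tissues it separated the arrays above 500 from those below. Between number ranges, with genotype in the fit, 4548 of 9078 probes differed in liver and 4859 in brain (limma, adjusted p under 0.05). Both genotypes were present in each range. In fat the first component held 30.9% of the variance. Fat_WT_138, Fat_WT_139, Fat_WT_148 and Fat_WT_165 lay at scores of -28.5 to -18.8 and the 6 KO arrays at 4.2 to 21.3, while Fat_WT_135 and Fat_WT_136 lay at 6.0 and 13.7.

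**Figure D2:**
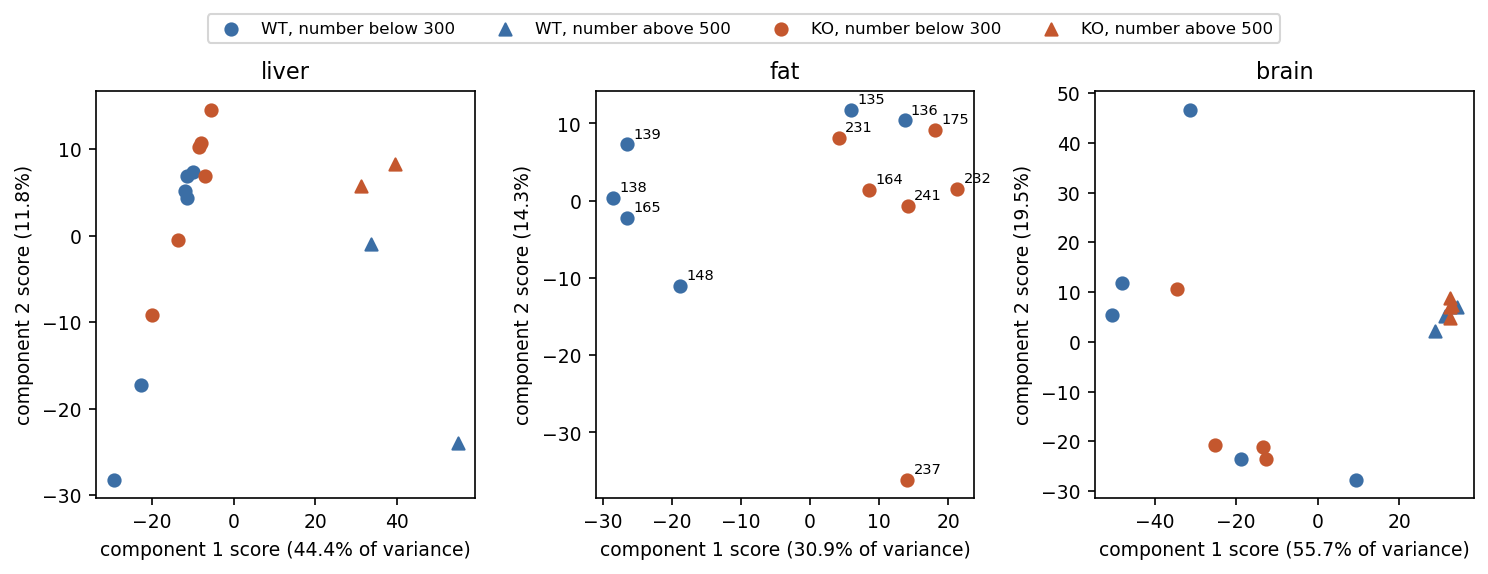
Scores of each array on the first 2 principal components within liver, fat and brain, with the share of variance on each axis; blue marks WT, orange marks KO, circles are animals numbered below 300 and triangles those above 500. In liver and brain the triangles lie apart from the circles, and in fat the arrays Fat_WT_135 and Fat_WT_136 lie among the KO arrays on component 1.

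The comparison of KO with WT liver asked which transcripts differ in liver when Surf1 is disrupted. At an unadjusted p under 0.05 there were 493 probes, where a share of 0.05 is 413. Other splits of the samples gave a median of 263. With limma, 0 of 8260 probes passed an adjusted p of 0.05. The smallest adjusted p was 0.105. The probes of smallest p were all detected on 16 of 16 arrays. ILMN_2831669 was 1.05 log2 higher in KO (SE 0.20), at 10.99 ± 0.34 (SD, n = 8) against 9.94 ± 0.52 (SD, n = 8) in WT, and ILMN_3160335 was 0.87 higher (SE 0.17), each with 7 of 8 KO samples above every WT sample. ILMN_2661650 differed by -0.64 (SE 0.12), at 13.18 ± 0.28 (SD, n = 8) in KO against 13.82 ± 0.21 (SD, n = 8) in WT, with 8 of 8 KO samples below every WT sample, and ILMN_1227212 by -0.71 (SE 0.14). The limma adjusted p was 0.105 for each of these probes, so none passed. Below and above the number gap the differences were 1.07 and 0.99 for ILMN_2831669, 0.91 and 0.77 for ILMN_3160335, -0.64 and -0.63 for ILMN_2661650, and -0.62 and -0.98 for ILMN_1227212, with 6 animals per genotype below 300 and 2 above 500. The probes were picked on these same samples, so the 2 ranges are no independent check of each other. With the number range as a covariate 14 probes passed, with animals below 300 alone 2 did, and with the 4 animals above 500 alone 6 did; array weights gave 166, 1 fit over all 44 arrays gave 57, and leaving out Liver_WT_679 or Liver_Surf1_KO_164 gave 6 or 3.

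In the same comparison in fat, 1368 of 9099 probes had an unadjusted p under 0.05. A share of 0.05 is 455, and other splits of the samples gave a median of 384. Past the threshold were 3 probes, 1 higher and 2 lower in KO. ILMN_2721357 showed the largest of these differences, -2.94 log2 (SE 0.45), or 7.66-fold lower in KO. It stood at 6.11 ± 1.10 (SD, n = 6) in KO against 9.05 ± 0.78 (SD, n = 6) in WT, was detected on 11 of 12 fat arrays, and was detected on 0 liver and 0 brain arrays. Some KO values lay near background, and the difference was -1.81 without background correction and -1.80 on the authors' processed values. ILMN_1243722 was 2.14-fold lower in KO, at 10.98 ± 0.26 (SD, n = 6) against 12.08 ± 0.34 (SD, n = 6), with a KO minus WT of -1.10 log2 (SE 0.16). ILMN_1240702 was 2.26-fold higher in KO, at 7.68 ± 0.16 (SD, n = 6) against 6.51 ± 0.44 (SD, n = 6), with a KO minus WT of 1.17 log2 (SE 0.18). This difference was 0.65 without background correction and 0.64 on the authors' processed values, and its limma adjusted p was 0.0510 without the filter on dim probes. For each of these probes the limma adjusted p was 0.0318, and 6 of 6 KO samples lay beyond every WT sample. The next probe, ILMN_2420538, was 0.74 log2 higher (SE 0.13) with a limma adjusted p of 0.0511 and did not pass. For ILMN_1240702, KO minus WT was 0.77 log2 in liver (SE 0.22, limma adjusted p = 0.318) and 1.17 in brain (SE 0.39, limma adjusted p = 0.999), neither past the threshold. These differences lay in the animals below 300. There liver stood at 7.99 ± 0.33 (SD, n = 6) in KO against 6.99 ± 0.57 (SD, n = 6) in WT, and KO minus WT was 1.76 in brain, with brain at 8.58 ± 0.33 (SD, n = 4) in KO against 6.82 ± 0.67 (SD, n = 5) in WT. Above 500 it was 0.06 in liver and 0.07 in brain, with brain at 8.92 ± 0.30 (SD, n = 4) in KO against 8.85 ± 0.15 (SD, n = 3) in WT. All fat samples were from animals below 300, so the fat difference could not be read in the other range.

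**Figure D3:**
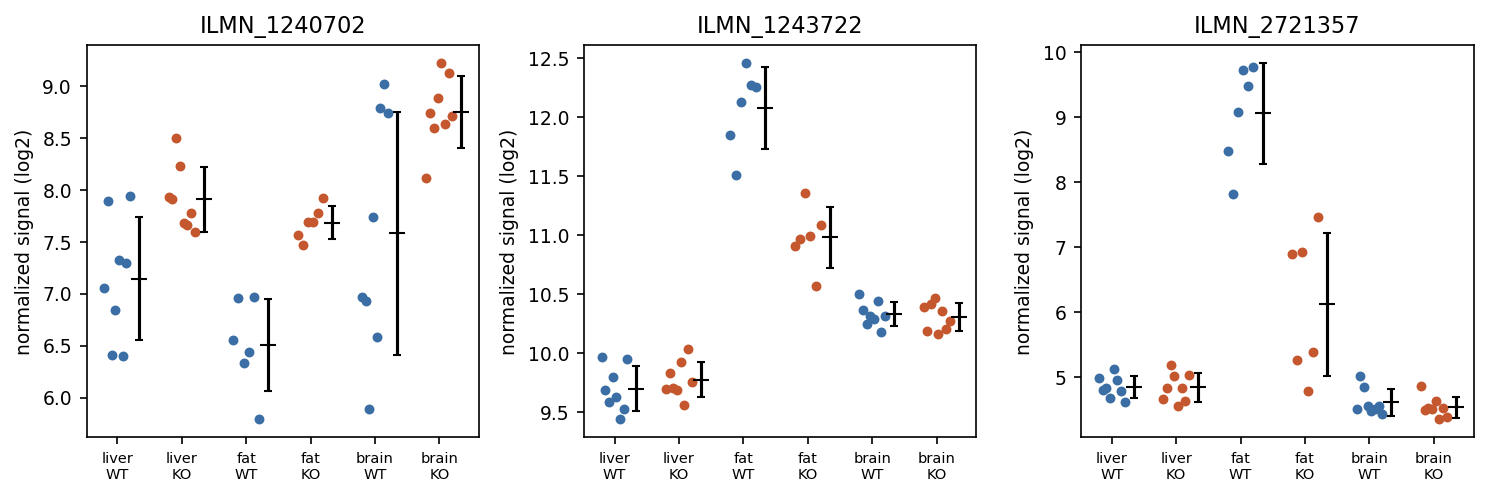
Normalized log2 signal (vertical axis) of each sample for the 3 probes that passed the threshold in fat, by tissue and genotype; blue points are WT, orange points are KO, and the bar beside each group is the mean ± SD. In fat, 6 of 6 KO samples lie beyond every WT sample for each probe, while ILMN_2721357 lies near background in liver and brain.

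The count in fat depended on single animals. It was 332 without Fat_WT_136, 98 without Fat_WT_135 and 9 without Fat_Surf1_KO_231. It was 0 without Fat_WT_138, Fat_WT_139, Fat_WT_165, Fat_Surf1_KO_164, Fat_Surf1_KO_175 or Fat_Surf1_KO_232, and 1 without Fat_Surf1_KO_241. Each of the 3 probes passed in 4 of these 12 fits, with limma adjusted p values up to 0.125. Their direction could not change, since all KO samples lay beyond every WT sample. KO minus WT ranged from 1.03 to 1.27 log2 for ILMN_1240702, from -1.21 to -1.01 for ILMN_1243722 and from -3.20 to -2.67 for ILMN_2721357. The count was 267 in 1 fit over all 44 arrays, which takes its spread from the 3 tissues together, and it was 5 with cyclic loess, 6 with detection required on every array and 5 with all detected probes as separate tests.

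In brain cortex, 224 probes had an unadjusted p under 0.05, where a share of 0.05 is 464. Other splits of the samples gave a median of 144. With limma, 0 of 9280 probes passed the threshold. The probe of smallest p, ILMN_1224421, differed by -0.96 log2 (SE 0.15), at 5.89 ± 0.25 (SD, n = 8) in KO against 6.85 ± 0.31 (SD, n = 8) in WT. Its limma adjusted p of 0.0535 did not pass, and 7 of 8 KO samples lay below every WT sample. Its difference was -1.03 below 300 and -0.80 above 500, on the same samples that picked it. The same probe differed by -0.80 in fat (SE 0.24, limma adjusted p = 0.146), and in liver it was detected on 2 of 16 arrays and not tested. ILMN_2642969 was 0.94 log2 higher in KO brain (SE 0.22, limma adjusted p = 0.999), ILMN_1256564 was 0.62 higher (SE 0.12, limma adjusted p = 0.303) and ILMN_1235580 differed by -0.77 (SE 0.20, limma adjusted p = 0.999), with -0.37 above 500 and a KO mean of 5.66 against 6.66 in WT below 300. With animals above 500 alone 17 probes passed, with those below 300 alone 0 did, and with the number range as a covariate 1 did. The count was 6 in 1 fit over all 44 arrays, 2 with array weights, and 1 without Brain_WT_1048, without Brain_Surf1_KO_231, without the intensity trend, with joint normalization or with detection required on every array.

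The title of the series speaks of effects that depend on the tissue, so the difference of the KO effect between tissues was tested itself. Between liver and fat, 40 of 7558 probes had a KO effect that differed (limma interaction, adjusted p under 0.05). The smallest p belonged to ILMN_1240943, which was 0.68 log2 higher in KO liver and differed by -2.54 in KO fat, a difference of 3.22 (SE 0.43, limma adjusted p = 1.36e-05). It was not among the probes past the threshold within liver or fat. Next was ILMN_1243722, with 0.08 in liver and -1.10 in fat (difference 1.18, SE 0.17, limma adjusted p = 2.61e-05). Between fat and brain the effect of 14 of 7858 probes differed, led by ILMN_1243722 (difference -1.07, SE 0.17, limma adjusted p = 0.000447). ILMN_2745370 was 0.86 higher in KO fat and differed by -1.16 in KO brain (difference 2.02, SE 0.37, limma adjusted p = 0.00587). It was not among the probes past the threshold within fat or brain. Between liver and brain 0 of 7134 passed with limma, with 274 at an unadjusted p under 0.05 where a share of 0.05 is 357. These tests shared 1 spread among all tissues, and the counts were 123 and 48 on the authors' processed values, 66 and 42 without the filter on dim probes, and, between fat and brain, 5 without the 4 brain arrays with the fewest detected probes.

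No probe passed the threshold in more than 1 tissue with limma, which follows from the 0 probes past it in liver and in brain. In the fit over all 44 arrays 1 deposited symbol passed in the same direction in more than 1 tissue. It was counted by name, so its probe may differ between the tissues. At an unadjusted p under 0.05 in the same direction, liver and fat shared 37 probes where independent lists would share 29.2. Liver and brain shared 13 against 3.6, and fat and brain shared 19 against 10.6. Many samples of different tissues carried the same number, so if these are animal numbers the lists were not independent. Whether this accounts for the shared probes was not tested.

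Gene lists fixed in advance were tested under the deposited names, which the marker genes did not bear out. With camera in limma, 0 of 34 pathway lists passed an adjusted p of 0.05 in liver, fat or brain, with 5, 2 and 3 lists at an unadjusted p under 0.05 and smallest adjusted p values of 0.151, 0.669 and 0.0796. Of the cell type marker lists, 0 of 8, 0 of 10 and 0 of 7 passed, with 0, 1 and 0 at an unadjusted p under 0.05, and the list of genes that neighbour Surf1 did not pass in any tissue (0 at an unadjusted p under 0.05). Adjusted over the list alone, 6 probes of pathway lists passed in liver, 15 in fat and 1 in brain, against 0, 0 and 0 probes of these lists over all probes tested. Because the probes in a list need not belong to its genes, these results describe no pathway.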

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

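The tests of exchanged arrays, of displaced identifiers and of array brightness (both of them) were chosen only after the result was seen, and the tests of other animals' RNA and of a shared state met the outcome written for them beforehand but are read as undecided by a rule added after the values were seen. The splits within number ranges and the regroupings of animals were added after the other splits were seen.

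Tissue markers did not follow their tissue under the deposited identifiers, with 7 of 154 marker probes over 1 log2 higher in their own tissue where 6.5 would be by chance. Whole tissues exchanged would move all hepatocyte markers to 1 tissue together, and at most 1 of the 11 hepatocyte probes was higher in any 1 tissue. This speaks against such an exchange as the only cause. With names that do not belong to their values the count would be low in any case. An exchange beside another fault, or of some arrays only, therefore stays open. A candidate explanation is that the identifiers were displaced along their own order, since a model of such a displacement, fitted to neighbouring probes of the same symbol, gave 11758 of 25697 probes an offset of -163 to -2 places. At that offset 58 of 98 marker probes (59.2%) were over 1 log2 higher in their own tissue, against 5 as deposited, 40 and 38 at 1 place after or before, and 4.4 by chance, but the lists were uneven, with 10 of 12 for oligodendrocytes, 1 of 13 for astrocytes (1 as deposited) and 4 of 8 for hepatocytes (4 at 1 place before). The marker counts were seen while the model was being set, so they are no independent check, no biological explanation was tested, and no gene is named from an offset.

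The second pattern was that the arrays Fat_WT_135 and Fat_WT_136 lay with the KO arrays, at 6.0 and 13.7 on the first component against -28.5 to -18.8 for the other 4 WT arrays. A batch like that of the number ranges in liver and brain stays open. On probes that differed the same way between the ranges in both tissues, the other 4 WT arrays overlapped the rest. Their scores were -0.22 to 0.40 against -0.45 to 0.27, a gap of -0.49 from the lowest of the first to the highest of the second. An overlap was written beforehand as arguing against such a batch. However, the probes that differed in both tissues were about as many as independent lists would share. The score may therefore mark no common batch, so it cannot decide. Brightness in common with the KO arrays is argued against. Of detected share, median and highest signal, 0 of 3 set the 2 arrays and the KO arrays apart from the other 4 WT arrays. Brightness of the 2 arrays alone stays open, since 3 of 6 of their values lay within the range of those WT arrays. Both of their highest signals (48290 and 43170) lay above that range (39310 to 43040, KO arrays 34140 to 43540). On 85 probes that tell animals apart, 1 of the 2 arrays (Fat_WT_136) matched the liver of another animal best (0.26 for Liver_Surf1_KO_231 against 0.12 for its own), and Fat_WT_135 matched its own (0.55), but only 9 of 12 fat arrays matched their own animal, so RNA of other animals cannot be told apart from the noise of this match. A state shared by the tissues of an animal stays open too, since the liver scores of 2 of the 2 animals (4.2 and 3.4) were nearer the KO mean among animals below 300, but the means there (0.4 for the other 4 WT and 0.7 for the 6 KO livers) were not separated, and over all livers the WT mean (0.4) was the nearer (KO -0.4), and a difference in the state of the fat itself was not tested.

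The KO effect differed between liver and fat for 40 probes and between fat and brain for 14, by a test of the difference itself. As many were reached in 2 of 100 regroupings within tissues for liver and fat, where the highest other count was 87, and in 4 of 100 for fat and brain, where it was 1072. With regroupings that also kept to the number ranges the numbers were 2 of 100 (highest other 76) and 4 of 100 (highest other 45). These treat the tissues of 1 animal as separate, and with 1 genotype per animal over its tissues the numbers were 3 of 100 (highest other 48) and 4 of 100 (highest other 24). All lay under the 5 of 100 set beforehand, those of fat and brain only just.

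In fat, 5 of 100 splits of the samples gave at least the 3 probes past the threshold, with 33 as the highest other count, so chance was not excluded. For the 1368 probes at an unadjusted p under 0.05 the number was 3 of 100, under the 5 of 100 set beforehand. The highest other count was 1508, above the real one, so chance was less likely there but not excluded. In liver, 21 of 100 splits gave at least 493 probes at an unadjusted p under 0.05 (highest other 2277), and 6 of 100 within number ranges did (highest other 704), so chance was not excluded. For the 166 liver probes found with array weights, 1 of 100 splits, the real one, reached the count over all samples (highest other 123). The same held within number ranges (highest other 74). This lay under the 5 of 100, but most other liver settings gave 0. The splits make no allowance for the choice of a setting, so chance was not excluded for the liver comparison. With the number range as a covariate, 1 of 100 splits within ranges, the real one, gave at least the 14 liver probes past the threshold (highest other 4). That count lay under the 5 of 100 too, with the same limit. However, 10 of 100 gave at least the 906 at an unadjusted p under 0.05 (highest other 1366). In brain, 37 of 100 splits gave at least 224 probes at an unadjusted p under 0.05 (highest other 3592), and 30 of 100 within number ranges did (highest other 1823). With the covariate 5 of 100 gave at least the 1 brain probe past the threshold (highest other 1996) and 44 of 100 gave at least 413 at an unadjusted p under 0.05 (highest other 3438), so chance was not excluded in brain.

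Where the real count was 0 every split reaches it, so 100 of 100 says nothing about chance for the probes past the threshold in liver (highest other 1) and brain (highest other 1549), for the difference between liver and brain (highest other 1496), or for the gene lists of liver, fat and brain (highest other 1, 2 and 4). Splits that called 1549 probes in brain over all samples, or 1996 within number ranges with the covariate, point to a structure of the brain samples other than genotype, which is not the number range alone. How the split that called 33 in fat grouped the samples was not examined, so it may follow genotype in part.

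Single samples lay far from the rest of their group in 6 of 48 groups of values, where about 1 in 20 would by chance. ILMN_2657141, named for Surf1, read 5.18 log2 in Liver_WT_679 against 4.60 to 4.79 in the other WT livers. ILMN_2883561, named for Surf1 too, read 5.28 in Liver_WT_136 (others 4.82 to 4.95), 5.33 in Liver_Surf1_KO_597 (others 4.78 to 5.04) and 5.42 in Brain_WT_165 (others 4.53 to 4.85). In Brain_Surf1_KO_175, 45.7% of probes were detected against 49.5% to 51.5% in the other KO brains. ILMN_1224421 read 6.46 in Brain_Surf1_KO_231 against 5.68 to 5.96 in the other KO brains.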

How the results depend on the processing

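The fits on animals above 500 alone, on animals below 300 alone between tissues, on all probes between tissues and without the 4 brain arrays with the fewest detected probes were chosen only after the result was seen. Over all settings, 78 counts stayed within 1.5 times the reported one and 42 did not, and the cause was not tested except where named. A count of 0 that stayed 0 was taken as staying, and most of the 78 were of this kind. Where the reported count was above 0, more counts moved than stayed. In liver the count of 0 became 166 with array weights, 57 in 1 fit over 44 arrays (a spread shared between tissues), 14 with the number range as a covariate, 2 below 300 and 6 above 500. Leaving out each sample gave 0 to 6 (6 without Liver_WT_679 and 3 without Liver_Surf1_KO_164). In fat the count of 3 became 5 with cyclic loess, 6 with detection on every array (fewer probes tested), 5 with all detected probes and 267 in 1 fit over 44 arrays. Leaving out each sample gave 0 to 332, with 332 without Fat_WT_136, 98 without Fat_WT_135, 9 without Fat_Surf1_KO_231, 1 without Fat_Surf1_KO_241 and 0 without Fat_WT_138, Fat_WT_139, Fat_WT_165, Fat_Surf1_KO_164, Fat_Surf1_KO_175 or Fat_Surf1_KO_232. Over 10 settings on all 12 fat samples (the reported one included), ILMN_1243722 (-1.21 to -1.06) and ILMN_2721357 (-3.00 to -1.80) passed in 10, and ILMN_1240702 (0.64 to 1.17) in 9, with a limma adjusted p of 0.051 without the filter (0.015 to 0.051 over these). Detection on every array was not among these settings. ILMN_2721357 was detected on 11 of 12 fat arrays and could not be tested there. With each sample left out they passed in 4 of 12 fits each, with limma adjusted p values up to 0.125. In brain the count of 0 became 1 with joint normalization, with detection on every array, with no trend and with the number range as a covariate, 2 with array weights, 6 in 1 fit over 44 arrays and 17 above 500. Leaving out each sample gave 0 to 1 (1 without Brain_WT_1048 or Brain_Surf1_KO_231).

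Of the lists, 1 passed in liver with no filter and 1 with cyclic loess. In brain 1 passed without the 4 brain arrays with the fewest detected probes. Between liver and fat the count of 40 became 123 on the authors' processed values and 66 with no filter. Between fat and brain 14 became 48 and 42 with these settings, and 5 without those 4 brain arrays. Between liver and brain 0 became 1 on the authors' processed values, with all probes and below 300. In 1 fit over 44 arrays 1 deposited symbol passed in more than 1 tissue. With the animal as a replicate block the counts between tissues were 48, 0 and 18, which included all 40 and 14 reported. The slide as a block was not run, since the files give no slides. The probes named for Surf1 lay at background, and under the deposited identifiers they need not measure Surf1. They passed in 0 of 6 tests as reported, on the authors' processed values, without background correction, with cyclic loess and with joint normalization.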

Other observations

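The test on probes with 2 levels was chosen only after the result was seen, and its limits were set after 3 were tried. The tests of inherited differences and of shared handling were written before their results, but the second is read as undecided by a rule added after its value was seen.

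Some probes varied together in the tissues of an animal. Of 9078 probes detected in all 3 tissues, 16 had a correlation over 0.9 between liver and fat across 12 animals, where permuted pairings of the animals gave at most 6 and a median of 0. The median correlation between liver and brain of these 16 probes across 9 animals was 0.93, against 0.08 over all probes, and 9 of the 16 were over 0.9. This is consistent with inherited differences between animals, as a hypothesis found on the same data, while handling shared by the tissues of an animal stays open. The median same-animal correlation over all probes was 0.09, under the bound written beforehand as arguing against such handling, but single animals ranged from -0.22 to 0.40, so a median does not exclude it for each of them. Of these 16 probes, 0 passed the threshold between KO and WT in fat.

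Some of these levels formed separate steps. Taking probes that split into 2 levels in both liver and brain, 27 were found, and for 9 the same animals were on each side in both tissues. In fat, 98 of 108 calls for these 9 probes matched the liver of the same animal, where 100 permuted pairings gave at most 84 and a median of 60, and for 6 probes all 12 animals matched. ILMN_3140158 had a step of 3.47 log2 in liver and 3.55 in brain, and was at the high level in 5 of 6 WT and 2 of 6 KO livers. Animals of a first cross between inbred strains carry the same alleles, so steps that follow the animal would be of interest beside the strain name in the labels. On these probes Fat_WT_135 and Fat_WT_136 matched the livers of their own animals in 9 and 8 of 9 calls, and 3 livers, Liver_WT_136 among them, held the same calls as Liver_WT_136.

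Other values bear on the identifiers. Under the deposited names, 50 of 85 cytoplasmic ribosomal protein probes (58.8%) and 29 of 55 proteasome probes (52.7%) were detected in all 3 tissues, against 35.3% of all probes. Bright neighbouring probes of the same symbol had a median correlation of 0.75 over the 44 arrays (737 pairs), and those of different symbols 0.73 (1669 pairs). Random pairs of bright probes had a median of 0.11, so neighbours correlated whatever their names. At the fitted offset the medians were 0.95 and 0.41, against 0.78 and 0.77 as deposited on the same probes, and the offset was fitted on these pairs.

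In liver and brain, 2425 probes differed between animals numbered below 300 and above 500 in both tissues, and 1475 of them differed the same way. The 2425 probes were about as many as independent lists would share, so this count shows no number range pattern common to the tissues. Whether more of them differed the same way than independent lists would give was not tested. No animal numbered above 500 gave both liver and brain. The labels do not say what the number ranges stand for.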
